A study of Mus musculus with 2 samples.

How the data were processed

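RNA was measured in 2 libraries from laser-captured areas of layer 5 of the mouse cerebral cortex, prepared with a Smart-seq type protocol, per the labels' protocols, with spike-in RNA added. The labels number the libraries as biological replicates and give both the same donor, so they were treated as separate areas of 1 animal, in 1 group of 2 libraries.

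The deposited gene and transcript tables gave an expected count per feature, an estimated number of reads that need not be whole because reads that map to several features are divided among them. The deposited tables also gave TPM, scaled by the authors to one fixed sum over all features of a library, spike-ins and mitochondrial genes included, and a posterior mean estimate of the same unit. The deposited transcript tables gave for each transcript its percent of the gene's expression. The assembly was mm10 and the annotation release M4, per the deposited text files that accompany the tables. The column layout was that of RSEM, while the program, its version, the aligner and the trimming were not given in the sources used here. The kit's strand setting was not given either, so reads of overlapping and antisense genes cannot be assigned with certainty.

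Totals were 26059117 and 28276843 expected counts. Reads carry no molecular identifiers, so intervals and floors cover counting error only. The libraries were checked for being copies of each other: chi-square per degree of freedom was 68.7 over 12591 genes with a summed count of at least 50, so they were treated as separate libraries. Symbols, gene classes and coordinates were taken from the GENCODE M21 annotation of GRCm38, the same assembly in another release. Of 43346 Ensembl gene rows, 42462 had a symbol. Of the list symbols fixed in advance 1 was not matched and 2 were matched through a synonym. Rows with a number in place of a gene, 26248 of them, held 20.3 and 5 counts, and Ensembl genes outside M21 held 0.155% ± 0.002 (SD, n = 2) of the counts. Both were left out of lists.

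Marker lists and the rule for named genes were fixed before the data were examined. From each list the rule took up to 4 members with the highest mean TPM and up to 2 under 1 TPM in both libraries, all members of the layer 5 list, the 10 genes with the highest and the 10 with the lowest log2 ratio at a mean of at least 20 TPM and a summed count of at least 100, the 10 most abundant nuclear protein-coding genes, and the isoform panel at 20 TPM or more. Aif1, Gad2, Slc32a1, Cldn11 and the genes of lists added later were named after their values were seen. App and Atp2b1 of the panel were listed with 1 transcript each and dropped out. Some genes that the rule took are not reported here.

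Values were log2(TPM + 1), a scale that understates changes of low genes. Detection was set at 1 TPM. A list's level was its median TPM, ranked among 10000 random lists of protein-coding genes of the same size. A list's difference was its median log2 ratio of replicate 1 over replicate 2, ranked among 10000 random lists matched in 20 classes of mean expression. Layer contrasts were differences of mean log2(TPM + 1) between lists. Counting error was simulated 20 times by binomial draws from the expected counts, rounded to whole numbers. Intervals of correlations and of median ratios came from 1000 bootstrap resamples of genes. Each side of every difference is 1 library, so no p-value was computed. TMM factors, used for CPM in an alternative, came from edgeR 4.0.16 in R 4.3.3 on rounded expected counts of nuclear genes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

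The procedure was tested on simulated data for replicate 1 against replicate 2 over 21474 genes, with noise milder than that between the real areas. It placed 98.5% of 67 genes changed 8-fold and 100% of 67 genes changed 16-fold beyond 4-fold in the right direction, 1.52% of 66 genes changed 2-fold, and 0 of 5128 unchanged genes. Of 100 unshifted lists of 12 genes 6% lay outside the central 95% of matched random lists, and of 100 lists shifted 2-fold 100% did. Simulated genes varied independently, and a 2-fold shift is larger than the medians of most lists that differed between the areas. These shares therefore do not describe small shifts or lists whose genes vary together.

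Alternatives were another pseudocount (0.1), other TPM and count minimums, CPM, TPM of nuclear genes alone, posterior mean TPM, medians in place of means, and leaving out each library or each layer 5 gene. Centring on the median gene, leaving out haemoglobin genes, counting the 5 most abundant unprocessed pseudogenes with the mitochondrially encoded genes and removing a trend with GC content and length were added after seeing the data. That trend was a cubic fit of the log2 ratio over 11841 genes at a mean of 1 TPM or more, and it explained 2.13% of the variance. The transcripts of those pseudogenes were compared with mitochondrial transcripts of the same annotation by their best match without gaps.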

Results

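The data were 2 RNA-seq libraries made from small areas of layer 5, a deep layer of the mouse cerebral cortex that holds large projection neurons. The tissue came from a wild-type male of the C57Bl6 strain aged 8 months. Each area covered about 8000 square microns, was cut out by laser capture and was entered in the labels as 50 cells. The labels number the libraries as biological replicates 1 and 2 but give both the same donor. They were taken here as areas of 1 animal, so that every SD below is the spread between those areas; whether they came from separate animals cannot be settled from the labels. There was 1 group and no contrast between conditions. The comparisons that the design allows are how layer 5 genes stand against those of other layers, which cell classes are present, and how alike the areas are. Replicate 1 held 26059117 expected counts and replicate 2 held 28276843. No test across animals was possible, and with 2 libraries an exact two-sided sign-flip test cannot go below p = 0.5.

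Layer 5 genes were present throughout and stood well above genes of the neighbouring layers. All 10 members of the layer 5 list reached 1 TPM, an abundance scaled for transcript length and library size, in both libraries. Pcp4, a calmodulin-binding peptide (ENSMUSG00000090223.1, chromosome 16 from 96467606 to 96525793 on mm10, as are all positions below), led with 2922 TPM in replicate 1 and 3599 TPM in replicate 2, and was the only layer marker among the 10 most abundant nuclear protein-coding genes. Fezf2, the transcription factor that specifies subcerebral projection neurons (chromosome 14, 12342094 to 12348189), had 18.6 and 24.5 TPM. Bcl11b, which acts downstream of it, had 11.0 and 6.91 TPM, and the transcription factor Etv1 had 19.0 and 23.8 TPM. Rbp4 reached 65.1 ± 32.6 TPM (SD, n = 2), Ldb2 59.8 ± 3.20, Sulf2 35.1 ± 14.4, Parm1 19.9 ± 15.4, Kcnn2 13.2 ± 5.95 and Crym 4.89 ± 4.24 on the same terms. The median of the list was 22.0 TPM in replicate 1 and 24.1 TPM in replicate 2, at the 98.9 and 99.1 percentiles of 10000 random lists of protein-coding genes. The random lists also held genes that were not detected, so these ranks show expression and not enrichment of layer 5.

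On the log2(TPM + 1) scale, the layer 5 list lay 3.61 ± 0.01 (SD, n = 2) above the mean of the 4 other layer lists. It lay 2.34 ± 0.30 above the layer 2/3 list, 3.79 ± 0.12 above layer 4, 3.56 ± 0.41 above layer 6 corticothalamic and 4.76 ± 0.20 above layer 6b. Each of these differences exceeded the spread between the areas, which leaves out the variation among the genes of a list. Without Pcp4 the difference to layer 2/3 was 1.43 in replicate 1 and 1.79 in replicate 2. The closeness of the areas belongs to list means: with list medians the difference to the mean of the 4 lists was 2.87 in replicate 1 and 3.68 in replicate 2, and that to layer 2/3 was 1.36 and 3.01. The lists hold different genes, so the size of each difference depends on which genes were chosen.

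Genes of other layers were low with a few exceptions. In the layer 2/3 list, Lamp5 reached 112 ± 6.46 TPM (SD, n = 2), while Cux1 had 9.12 ± 1.96, Calb1 5.98 ± 5.47 and Wfs1 5.29 ± 0.87 TPM, and Otof stayed under 1 TPM in both areas. In the layer 4 list, Rorb had 8.47 ± 3.71 TPM, Kcnh5 3.47 ± 2.55 and Whrn 2.24 ± 2.94, and Rspo1 and Scnn1a were under 1 TPM. In the layer 6 corticothalamic list, Rprm had 15.2 ± 12.2 TPM, Tle4 6.97 ± 3.37 and Foxp2 2.58 ± 0.42. Ntsr1 was under 1 TPM and Osr1 had 0 counts in both libraries. No layer 6b gene reached 1 TPM in both areas. A count of 0 allows up to 0.115 CPM (counts scaled to library size) in replicate 1 and 0.106 in replicate 2, for counting error only. Within layer 5, the extratelencephalic list reached 1 TPM in both areas for 3 of 6 members, led by Bcl6 at 2.66 ± 0.95 TPM, and Chrna6 had 0 counts. All 4 intratelencephalic genes did so, led by Deptor at 11.4 and 38.5 TPM and Hsd11b1 at 6.76 and 16.2 TPM. Of the near-projecting list 4 of 6 did, led by Lypd1 at 18.5 and 8.56 TPM.

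**Figure D1:**
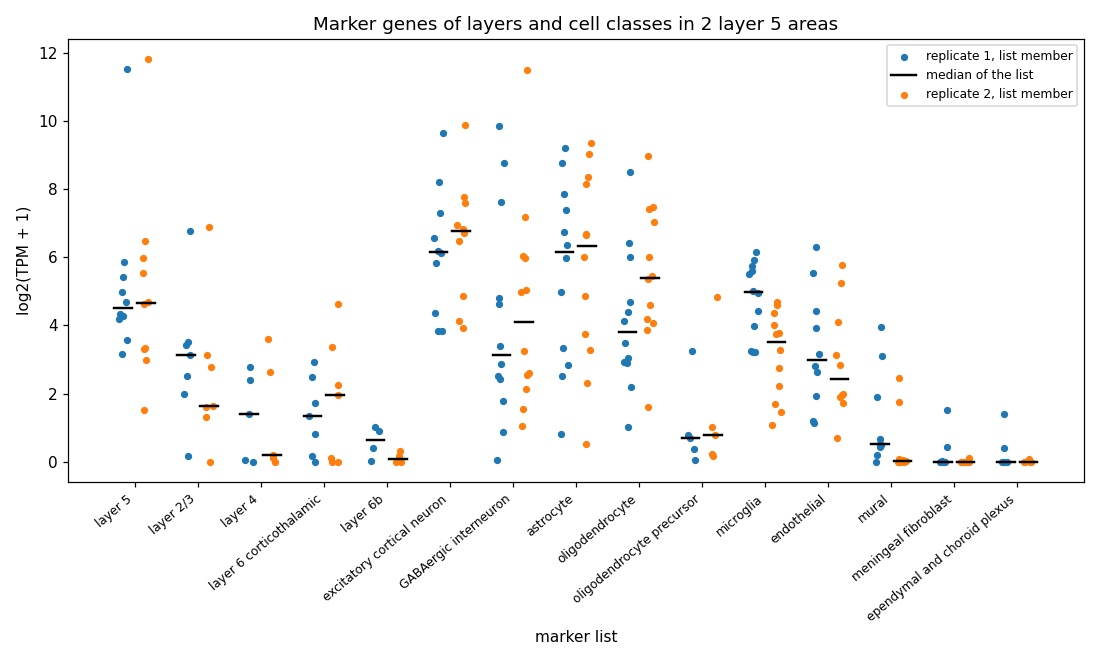
Expression of marker list members in the 2 areas, where the vertical axis is log2(TPM + 1), the horizontal axis gives the list, each point is 1 gene in replicate 1 or replicate 2, and black bars are list medians. The highest layer 5 point is Pcp4 at 2922 TPM in replicate 1 and 3599 TPM in replicate 2, and the fibroblast and ependymal lists have medians at or near 0.

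Neuronal, astrocytic, oligodendrocytic and microglial genes were all present, and genes of meninges and choroid plexus were nearly absent. All 12 pan-neuronal genes reached 1 TPM in both areas, with Snap25, a vesicle fusion protein, at 6480.4 ± 687 TPM (SD, n = 2), Uchl1 at 908 ± 103, Stmn2 at 557 ± 4.89 and Eno2 at 506 ± 27.0. All 10 excitatory genes did so, led by Nrgn at 875 ± 104, Arpp21 at 256 ± 54.0 and the kinase gene Camk2a at 174 ± 26.9 TPM. Of the 12 GABAergic genes, 10 reached 1 TPM in both areas. Of the 12 astrocyte genes 11 did, with Apoe at 616 ± 41.2 TPM, Aldoc at 478 ± 57.8, Clu at 280.5 ± 69.0 and Glul at 224 ± 82.5, while Gfap stayed under 1 TPM. All 12 oligodendrocyte genes reached 1 TPM in both areas, among them the myelin genes Mbp at 429 ± 97.0 and Mobp at 107 ± 32.5 TPM, and so did all 12 microglial genes, among them C1qb at 45.1 ± 36.0 TPM. Endothelial genes did so for 9 of 10 members, with Ly6c1 at 57.1 ± 28.3 TPM.

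Of the 9 mural genes only Rgs5 and Vtn reached 1 TPM in both areas. In the oligodendrocyte precursor list Olig1 alone did, at 8.51 and 27.4 TPM, and Cspg4 and Gpr17 were under 1 TPM. None of the 6 meningeal fibroblast genes and none of the 5 ependymal and choroid plexus genes did so in both areas. The collagen genes Col1a1 and Col1a2 stayed under 1 TPM in both, and Foxj1, a transcription factor of ciliated cells, had 0 counts in both. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in both areas, with 22.9 ± 4.33 TPM for Ddx3y, and Xist had 7 counts in replicate 1 and 0 in replicate 2. The animal was labelled male.

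Synaptic and metabolic genes were among the most abundant. The synaptic vesicle release list had medians of 88.4 and 121 TPM, led by Rab3a at 634 ± 161 (SD, n = 2) and Cplx1 at 294 ± 91.3 TPM. Among the glutamate receptors, 14 of 15 genes reached 1 TPM in both areas, led by Gria2 at 207 ± 25.4, Grin1 at 105 ± 32.2 and Gria3 at 86.3 ± 3.61 TPM, and Grin2d stayed under 1 TPM. Among the GABA-A receptors 12 of 13 did. Among the voltage-gated channels 21 of 23 did, among them the sodium channel subunit Scn2b at 203 ± 47.2 TPM. Ribosomal protein genes had medians of 274 and 236 TPM, led by Rpl41 at 1288 ± 192 TPM, and nuclear oxidative phosphorylation genes 682 and 610.2 TPM, led by Cox8a at 3498 ± 164 TPM. Immediate early genes, which respond to activity within minutes, had medians of 4.50 and 7.93 TPM, led by Egr1 at 57.3 ± 21.9, Junb at 14.6 ± 6.37, Dusp1 at 12.4 ± 0.27 and Arc at 11.8 ± 6.36 TPM, and Egr2 had 0 counts. In all, 11 of the 28 fixed lists had medians above the central 95% of random lists in both libraries, and none lay below it in both. Random lists were drawn from all 21474 protein-coding genes, of which 11050 reached 1 TPM in both areas, so a high rank shows little beyond expression. Small lists could hardly lie below: the ependymal and choroid plexus list, with medians of 0 TPM, lay at the 10.4 and 11.7 percentiles.

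The most abundant nuclear protein-coding genes included Snap25, Calm2 at 6350 ± 78.3 TPM (SD, n = 2), Ppia at 5705 ± 627 and Fth1 at 4986 ± 82.8 TPM, as well as Tmsb4x, Cox8a, Pcp4, Ubb and Usmg5. Calm2, Ppia, Fth1 and Ubb have near-identical relatives or pseudogenes, so their values are uncertain. All 37 mitochondrially encoded genes, ribosomal and transfer RNA included, held 5.42% ± 0.49 of all counts, spike-ins 7.57% ± 0.53, ribosomal protein genes 0.968% ± 0.13 and the 10 most abundant genes of each library 7.83% ± 0.59. There were 12.2 ± 0.92 endogenous counts per spike-in count. Among the mitochondrially encoded protein genes, mt-Atp8 had 14635 ± 1780 TPM and mt-Atp6 12258 ± 663 TPM. The transcript of the chromosome 1 pseudogene Gm10925 is identical to mt-Atp6 over all of its 678 bases, and 4 more pseudogenes beside it match mt-Co3, mt-Co1, mt-Co2 and mt-Nd3 at 98.8% of bases or more, so the values of these genes are uncertain. With these 5 pseudogenes, an alternative added after seeing the data, the mitochondrial share was 7.92% ± 0.66.

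The areas were alike over most genes. Of 21474 protein-coding genes, 11821 reached 1 TPM in replicate 1 and 11664 in replicate 2, with 11050 in both and 12435 in either. Across those 12435 genes, which are not independent replicates, Spearman's rho was 0.941 and Pearson's r of log2(TPM + 1) was 0.949. The median absolute log2 ratio was 0.50 between 1 and 5 TPM, 0.36 between 5 and 20, 0.26 between 20 and 100, 0.18 between 100 and 500 and 0.20 above 500 TPM. Counting error alone would give 0.08, 0.05, 0.03, 0.02 and 0.01 in the same classes, a lower limit that leaves out amplification and the difference between areas. Between 20 and 100 TPM, 96.8% of the genes lay within 2-fold. At a mean of 20 TPM or more the log2 ratio had an SD of 0.49 over 4422 genes and 0.28 over 42 spike-in transcripts.

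Cell class genes differed between the areas. Microglial genes were higher in replicate 1, where 11 of 12 members were more than 2-fold higher and the median log2 ratio was 1.70, at the 100th percentile of 10000 random lists matched on expression. The complement subunit genes C1qb and C1qc had 70.5 against 19.6 and 47.8 against 8.75 TPM, and the signalling adaptor Tyrobp 52.3 against 24.8 TPM. Aif1, named after its value was seen, was the exception at 14.7 and 15.3 TPM. Oligodendrocyte genes were higher in replicate 2 for all 12 members, with a median log2 ratio of -1.39 at the 0th percentile. Mbp had 360.4 against 498 TPM and Trf, the transferrin gene, 24.7 against 171 TPM. The 4 haemoglobin genes were higher in replicate 2, and the erythrocyte list had a median log2 ratio of -4.96 at the 0th percentile, while Alas2 had 1.48 and 0.61 TPM. Haemoglobin gene pairs share reads, so the split within each pair is uncertain.

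Other lists, neuronal and not, differed less by their medians under the main settings. Synaptic vesicle release genes were higher in replicate 2 for 14 of 16 members, with a median log2 ratio of -0.48 at the 0th percentile. Vamp2, a vesicle fusion protein, had 194 against 349 TPM and the vesicle GTPase Rab3a 520.0 against 747. Immediate early genes were higher in replicate 2 for 11 of 12 members, with a median of -0.50 at the 0.37 percentile, and Arc had 7.31 against 16.3 TPM. Layer 5 intratelencephalic genes had a median of -0.82 at the 1.16 percentile, with Deptor at 11.4 against 38.5 TPM and Tcerg1l going the other way at 4.81 against 1.08. Pan-neuronal genes had a median of -0.22 at the 1.51 percentile and excitatory genes -0.31 at the 2.03 percentile. Ribosomal protein genes were higher in replicate 1 for 61 of 72 members and nuclear oxidative phosphorylation genes for 72 of 84, each with a median log2 ratio of 0.23 at the 100th percentile. Mural genes at 0.52 and the 99.2 percentile, GABA-A receptor genes at 0.23 and the 98.4 percentile, and layer 2/3 genes at 0.40 and the 97.9 percentile were also higher in replicate 1. Of the mural genes, 6 of 9 were under 1 TPM in both areas.

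In all, 13 of 28 fixed lists lay outside the central 95% of matched random lists. By chance 1.4 would be expected if the genes within a list varied independently, as those of random lists do. Genes of 1 cell class need not meet this condition, so 1.4 may be too low. The percentiles describe these libraries and have no replicate check. With CPM the excitatory list moved to a median of -0.20 at the 6.90 percentile and the layer 2/3 list to 0.22 at the 83.3 percentile. A trend with GC content and length was then removed, an alternative added after seeing the data. The pan-neuronal list moved to a median of -0.19 at the 3.47 percentile and the excitatory list to -0.20 at the 8.36 percentile. The same removal lowered the median of the oxidative phosphorylation genes to 0.098 and of the ribosomal protein genes to 0.13, both still above the central 95%. The mural median was 2.20 with a pseudocount of 0.1, 1.09 with CPM, 1.89 over members at 1 TPM and 1.80 after the removal, so its size is not fixed by these data. The layer 2/3 median was 0.95 and the immediate early median -0.79 with a pseudocount of 0.1, the layer 2/3 median was 0.67 after the removal, and the GABA-A receptor median was 0.38 with CPM. The layer 5 list did not stand apart, with a median log2 ratio of -0.20 at the 17.1 percentile and members going both ways, and neither did the astrocyte list at -0.19 and the 9.97 percentile. The layer 6 corticothalamic list lay inside at -0.24 and the 11.4 percentile, but with CPM it was at -0.95 and the 0.15 percentile.

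**Figure D2:**
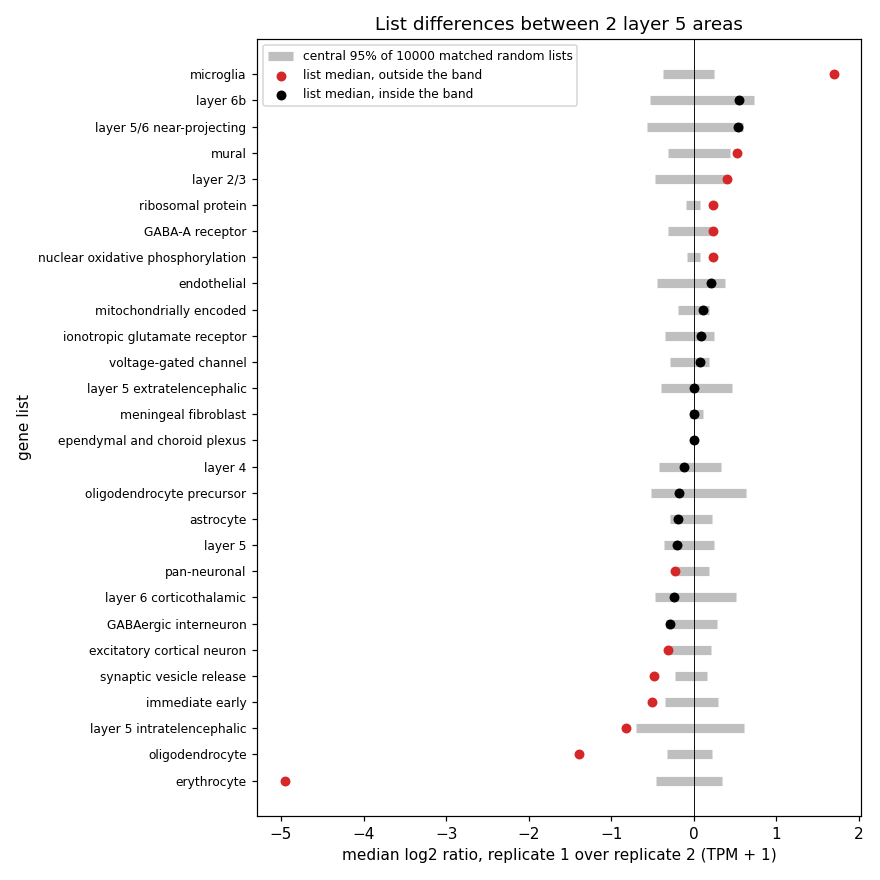
Median log2 ratio of replicate 1 over replicate 2 for the 28 fixed lists, where the horizontal axis is on the log2(TPM + 1) scale, each point is a list median, and each grey band is the central 95% of 10000 random lists matched on expression. The microglia list at 1.70, the oligodendrocyte list at -1.39 and the erythrocyte list at -4.96 lie farthest from their bands.

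The genes that differed most included 3 of the fixed GABAergic list, Pvalb, Gad1 and Sst. At a mean of 20 TPM or more, 21 of 4422 protein-coding genes were beyond 4-fold, 10 higher in replicate 1 and 11 in replicate 2. Folds below are ratios of counts per total with exact Clopper-Pearson 95% intervals, which cover counting error only. Pvalb, the calcium buffer of a class of fast-spiking interneurons (ENSMUSG00000005716.12), on chromosome 15 from 78191114 to 78206400, had 918 against 145 TPM, 6.62-fold higher in replicate 1 (6.36 to 6.89). Gad1, a GABA-synthesising enzyme on chromosome 2 from 70553072 to 70602014, had 438 against 65.2 TPM, 7.02-fold higher (6.80 to 7.26), whereas Gad2, the other such enzyme, named after its value was seen, had 23.9 and 31.8 TPM. The neuropeptide gene Tac1 was 24.4-fold higher in replicate 1 (18.6 to 32.5) and Cox6a2, a cytochrome oxidase subunit, 7.51-fold (6.42 to 8.81). The potassium channel gene Kcnc1 was beyond 4-fold in TPM, at 106 against 24.9, but 2.75-fold higher by counts (2.59 to 2.93), and its log2 ratio fell within 4-fold with CPM, at 1.42.

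Sst, the somatostatin gene on chromosome 16 from 23889573 to 23890958, went the other way, with 2092 counts and 194 TPM in replicate 1 and 31816 counts and 2859 TPM in replicate 2, a fold whose interval ran from 13.4 to 14.7. The neuropeptide genes Tac2, with 5 and 3115 counts, and Crh, with 1 and 2749 counts, were 574-fold (246 to 1769) and 2533-fold (454 to 100100) higher in replicate 2. Synpr, a synaptic vesicle protein, was 8.47-fold higher (7.82 to 9.19). The GABAergic list as a whole lay inside the central 95%, with a median log2 ratio of -0.28 at the 4.78 percentile, with 4 members higher in replicate 1 and 8 in replicate 2. This value depended on the setting: it lay at the 2.06 percentile with CPM, and after the GC content and length trend was removed it turned to 0.088 at the 77.8 percentile.

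The remaining genes beyond 4-fold included members of the microglial, oligodendrocyte and erythrocyte lists and genes of no fixed list. Spp1, the osteopontin gene on chromosome 5 from 104435118 to 104441050, had 7813 counts in replicate 1 and 1 in replicate 2, an 8478-fold ratio whose interval ran from 1521 to 334902. Tnni3, a cardiac troponin subunit, had 666 counts in replicate 1 and 0 in replicate 2. By the exact interval it was at least 195-fold higher in replicate 1, and 241-fold when set against a floor of 3 counts in replicate 2. Laptm5 was 7.12-fold (5.90 to 8.66), C1qc 5.73-fold (4.95 to 6.66) and Lgals1 4.75-fold (4.14 to 5.48) higher in replicate 1. Apod was 7.69-fold (6.87 to 8.63) and Trf 7.25-fold (6.65 to 7.90) higher in replicate 2, and Cldn11, named after its value was seen, was 5.73-fold (5.01 to 6.57) higher. The haemoglobin genes completed the set: Hba-a1 was 31.3-fold (22.8 to 43.5), Hba-a2 33.5-fold (26.6 to 43.2), Hbb-bs 35.9-fold (26.2 to 49.5) and Hbb-bt 174-fold (68.5 to 978) higher in replicate 2.

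**Figure D3:**
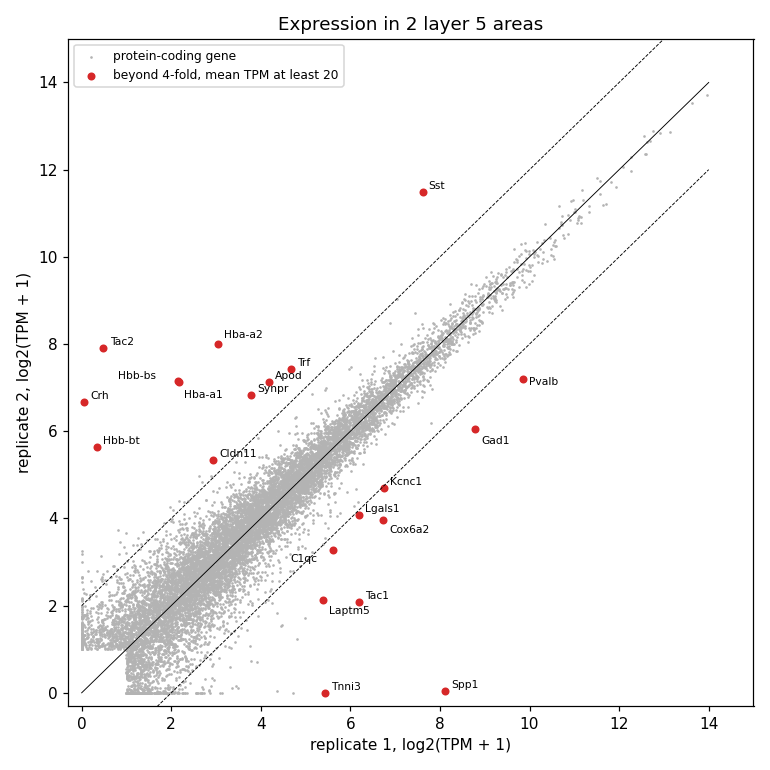
Expression of 12435 protein-coding genes in replicate 1 (horizontal) against replicate 2 (vertical), both as log2(TPM + 1); each grey point is 1 gene, red points are the 21 genes beyond 4-fold at a mean of 20 TPM or more, the solid line marks equal values and the dashed lines 4-fold. Sst, Tac2 and Crh lie above the upper dashed line, and Pvalb, Gad1 and Spp1 below the lower.

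Dominant isoforms were mostly shared. Of 3117 genes with at least 2 listed transcripts and 20 TPM in both areas, 2786 had the same most abundant transcript. This was 89.4% (Wilson 95% interval 88.3 to 90.4, which treats genes as independent). A random choice among the listed transcripts would give 21.9%. That baseline supposes equal use of all listed transcripts, so exceeding it says little. In the panel of neuronal genes 17 of 18 kept the same dominant transcript. Snap25-201 held 99.3% ± 0.37 (SD, n = 2) of its gene, Pkm-202 98.5% ± 0.46, Cdc42-201 78.5% ± 1.18, Ppp3ca-201 61.9% ± 0.32 and Gria2-202 48.1% ± 0.83. The share of Camk2b-209 differed more, at 60.2% and 78.5%, as did that of Camk2a-203, at 83.2% and 65.6%. Grin1, the obligatory NMDA receptor subunit, was the exception: the coding transcript Grin1-207 led in replicate 1 with 29.1% and Grin1-209, annotated as a processed transcript, led in replicate 2 with 39.4%.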

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

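Both tests of Ighm below were chosen after the result was seen. The gene classes here lay outside the protein-coding comparisons and held more counts in both areas than a count of 0 allows.

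Unprocessed pseudogenes held 2.53% ± 0.17 (SD, n = 2) of all counts. Their leading gene was Gm28437 on chromosome 1 from 24613189 to 24613971, with 17985 and 17925 TPM, and Gm29216, Gm10925, Gm28661 and Gm28438 beside it were the next most abundant. These 5 held 2.63% of counts in replicate 1 and 2.38% in replicate 2 and are near-identical copies of mitochondrial genes, with Gm28437 the same as mt-Co3 over all of its 783 bases, so the reads cannot be assigned between the copies with certainty. Long intergenic RNAs held 1.83% ± 0.17, led by the nuclear RNA Malat1 with 25652 TPM in replicate 1 and 19681 TPM in replicate 2. Mitochondrial ribosomal RNA held 1.35% ± 0.23, led by mt-Rnr2, and is part of the 5.42% given for all mitochondrially encoded genes. Genes of the annotation class that awaits experimental evidence held 0.644% ± 0.14, led by Gm37376 on chromosome 19 from 5801941 to 5802393. This gene lies within the span of Malat1, from 5795690 to 5802672, so its counts are uncertain.

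Processed pseudogenes held 0.577% ± 0.07, led by Gm10123. Processed transcripts held 0.210% ± 0.003 with Snhg14 in front, and antisense genes 0.191% ± 0.009 with Kcnq1ot1. Transcribed processed pseudogenes followed at 0.104% ± 0.009, led by Gm1821. Smaller shares were 0.0278% for miscellaneous RNA, led by Rn7s2, 0.0272% for transcribed unprocessed pseudogenes, led by Tmem181b-ps, 0.0235% for bidirectional promoter RNAs and 0.0153% for sense intronic RNAs. Reads of pseudogenes and of their parent genes cannot be assigned with certainty where the sequences are nearly identical.

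Immunoglobulin constant genes held 0.0191% ± 0.006, led by Ighm, the constant region of the IgM heavy chain on chromosome 12 from 113418558 to 113422730. Ighm had 3750 counts and 122 TPM in replicate 1, and 5599 counts and 177 TPM in replicate 2. B cells or plasma cells would bring light chains and other B cell genes, yet the 8 measured genes of a B cell and plasma cell list together reached 0.0493% of Ighm's TPM in the library where they were higher, and Igkc, Iglc2 and Cd79a had 0 counts in both. Residual blood, as tracked by haemoglobin, would move Ighm alike, yet its log2 ratio lay 4.44 above the median of the 4 haemoglobin genes. The other erythrocyte gene, Alas2, was low and went the other way from haemoglobin, so how well haemoglobin tracks blood is uncertain. Ighg2c, an IgG heavy chain constant gene named after its value was seen, had 194 and 906 counts and a log2 ratio of -2.07. This lay between Ighm at -0.54 and the 4 haemoglobin genes, which ran from -4.95 to -5.29. Blood as the source of Ighg2c was not tested. For Ighm, B cells or plasma cells are argued against as the whole source, and blood only as far as haemoglobin tracks it. Reads from another transcript at this locus stay open, and no other biological explanation was tested.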

How the results depend on the processing

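Numbers of detected genes, lists above random in both libraries and lists that differed between libraries stayed within 1.5 times their main values under every alternative run, and no called value changed direction. Of the 13 lists that differed, 10 did so under every alternative. Of 1509 other values recomputed, 1402 stayed, 91 moved by more than their spread, 7 passed a threshold they had missed, 5 no longer passed one and 4 changed sign. The 4 were medians of lists inside the central 95%: after the GC content and length trend was removed the GABAergic list went to 0.088, the endothelial list to -0.043 and the mitochondrially encoded list to -0.075, and with CPM the voltage-gated channel list went to -0.0085. The layer 6 corticothalamic list passed with CPM, over members at 1 TPM and after the GC content and length trend was removed, the near-projecting, GABAergic and endothelial lists with CPM, and the oligodendrocyte precursor list over members at 1 TPM. Removing the GC content and length trend, leaving out haemoglobin genes, counting the chromosome 1 pseudogenes and centring on the median gene were chosen after seeing the data, and centring cannot change a percentile by its construction. Among the other values, those with a library left out were set against the SD of the libraries and stayed within it by construction. They are part of the 1402, so that number is no measure of robustness. Correlations moved with the genes admitted, the unit and the pseudocount. Spearman's rho was 0.958 without a TPM filter, 0.928 at 5 TPM, 0.95 with CPM and 0.921 over all Ensembl genes. Pearson's r was 0.976, 0.940, 0.937 and 0.938 in the same order. With a pseudocount of 0.1, over the same genes as the main value, Pearson's r was 0.896. The layer 5 difference stayed positive at 4.94 with a pseudocount of 0.1 (SD 0.28), 3.07 over members at 1 TPM, 3.76 with CPM, 3.27 with medians (SD 0.57 between the areas), 3.47 with posterior mean TPM, and 2.89 without Pcp4 to 3.92 without Crym. Between 20 and 100 TPM the spread was 0.24 with CPM. Genes beyond 4-fold numbered 63 at a mean of 5 TPM and 6 at 100 TPM, where more or fewer genes were tested, and 17 without haemoglobin genes. As shares of TPM, mitochondrially encoded genes held 8.30% and spike-ins 14.3%, since TPM weights short features more, and with their chromosome 1 pseudogene copies counted the mitochondrially encoded genes held 7.92% of counts. The same dominant isoform was found for 85.6% of genes at 5 TPM, 95.2% at 100 TPM and 99.6% where it held over 60% of the gene. Apart from the changes of gene set, the cause was not tested. With each library left out in turn, detected genes ran from 11664 to 11821, lists above random from 12 to 14, the layer 5 difference from 3.61 to 3.62, the mitochondrial share from 5.08% to 5.77% and the spike-in share from 7.19% to 7.94%. With nuclear TPM alone the mitochondrially encoded list has no value. No paired analysis was possible because there was 1 group. Depth limits what can be said of genes at 0 counts, for which 0.115 and 0.106 CPM remain possible.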

Other observations

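The tests of the parvalbumin part and of the somatostatin part on their own were chosen after their results were seen, and the second gene lists after the differences of the first lists, but before their own values, were seen. Neuropeptide genes as a list did not stand apart between the areas, with a median log2 ratio of -0.10 at the 14.9 percentile, although single members differed widely. Cck had 2355 and 2530 TPM, and Npy 27.2 and 61.5 TPM. Among members named after their values were seen, Cartpt had 62 counts in replicate 1 and 1 in replicate 2, and Pdyn 109 and 4.

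Pvalb and Sst moved apart between the areas. In second lists, which share no gene with the first, all 10 parvalbumin interneuron genes were higher in replicate 1, with a median log2 ratio of 1.51. Among them Btbd11 had 21.1 against 1.96 TPM and Kcns3 9.14 against 1.05. The size of that median depended on the setting, from 1.39 with posterior mean TPM to 2.68 with a pseudocount of 0.1. Chance gain or loss of single genes is argued against for the parvalbumin part, at the 100th percentile of matched random lists. The fitted trend with GC content and length did not account for it, since the list stayed at the 100th percentile after the removal, with a median of 1.91. That median covers only members at a mean of 1 TPM or more, so it is not over the same genes as 1.51. A trend that explained 2.13% of the variance could hardly move a median of this size, and bias of another form was not tested. Over all 21 genes beyond 4-fold, haemoglobin and glial genes included, the median absolute log2 ratio was 3.25 before and 3.28 after the removal. These genes were picked for a large ratio, and a trend that explained 2.13% of the variance could hardly move them. No conclusion is drawn from this value, which is no evidence on parvalbumin genes alone. The difference between the second lists also lay at the 100th percentile of random pairs, but the parvalbumin list carried it, since the second somatostatin list had a median of 0.04 at the 80.5 percentile, with 7 of 13 members higher in replicate 1 and 4 in replicate 2. The second somatostatin list holds none of Sst, Tac2 and Crh and does not settle their differences. For these 3 genes chance gain or loss was not told apart from a change in cells. No spike-in of 42 deviated by more than 0.87 on the log2 scale from their median. These 3 genes were picked for their difference, however, and spike-ins do not pass through dissection. No biological explanation was tested for the parvalbumin part, and Gad2, at 23.9 and 31.8 TPM, and Slc32a1, at 4.43 and 3.40 TPM, did not differ as Gad1 did.

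Microglial genes were higher in replicate 1 and oligodendrocyte genes in replicate 2. In second lists all 10 microglial genes were higher in replicate 1, with a median log2 ratio of 1.53, and 8 of 10 oligodendrocyte genes were higher in replicate 2, with a median of -1.32. A change in the share of neuronal RNA alone would move both the same way, yet their difference lay at the 100th percentile of random pairs. Chance gain or loss of single genes is also argued against, with the second microglial list at the 100th percentile and the second oligodendrocyte list at the 0th percentile. No biological explanation was tested, since there was 1 group.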
